A study of Mus musculus with 2 samples.

How the data were processed

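The series measured RNA of the C2C12 mouse myoblast line by long-read RNA sequencing, with 1 group of 2 biological replicates, 1 library each. Per the labels' protocol links, the platform was PacBio, and SIRV and Ambion mix 1 (ERCC) spike-in RNA was added. The deposited values are counts: whole reads per transcript model, 1 table per library, with no normalization, per the file headers. Every listed model had at least 1 read. Reads were placed on mm10 and models were compared with the GENCODE M21 annotation, per the accompanying text records. Tags in the deposited model files name TALON as the tool that built and classified the models, but its version, the aligner and the read filters are not given in the sources used here. Each library was quantified separately, so unannotated models carry names that are not shared between the libraries. The length in the deposited tables is that of the model, and for annotated models that of the annotation, not of the reads. Coordinates are 1-based and in mm10.

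Reads of all models of an annotated gene were summed per library, and CPM were computed over the reads on annotated genes. Totals were 2577735 and 2562327 reads, so a floor of 3 counts was 1.16 and 1.17 CPM. Correlations used log2(CPM + 1) over genes with at least 10 reads over both libraries, with a bootstrap of 1000 draws. Each such gene was tested with an exact two-sided binomial test of its reads against the split of the library totals, with Benjamini-Hochberg adjustment and a threshold of 0.05. A test on 2 libraries compares those libraries and has no error beyond counting. Gene lists were described by the median log2 ratio of their members, its percentile among 10000 random lists of the same size matched on mean expression in 20 strata, and a two-sided permutation p adjusted over 17 lists. Length was the read-weighted model length of a gene, and the length trend was a running median in 40 bins. Intervals of log2 ratios and shares are 95% intervals, Wilson for class shares and Clopper-Pearson for isoform shares, and cover counting error only.

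The 18 gene lists were fixed before the data were examined: myogenic regulators, differentiation, cell cycle, cell cycle exit, extracellular matrix, actin cytoskeleton, cytosolic ribosomal proteins, glycolysis, mitochondrially encoded genes, immediate early genes, stress, interferon response, bone, fat and cartilage, markers of other cell types, growth factor and Notch signalling, splicing regulators, long noncoding RNAs and isoform genes. The named genes were also set by a rule written beforehand. It took the 20 nuclear genes with the highest mean CPM, the 3 highest members of each list and its largest difference past the threshold, and 11 genes by name (Myod1, Myf5, Myog, Pax7, Myh3, Ckm, Mki67, H19, Meg3, Igf2, Malat1). It further took the 10 largest differences in each direction with at least 50 reads, up to 15 isoform genes, the 10 largest differences in isoform share, the 10 most read NIC or NNC models in both libraries, and 5 intergenic and 5 antisense loci. The values of 2 genes that this rule took are not reported here. Genes copied by a pseudogene were named after their values were seen.

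Transcript models with more than 1 exon were matched between libraries by their exact intron chain. Isoform use was tested per gene with Fisher's exact test, two-sided, of the most used model against the rest, for genes with at least 20 reads in each library and 2 or more models with at least 5% of reads, without the Genomic class. Unannotated 1-exon models of a gene were pooled, a choice made after it was seen that names not shared between the libraries forced differences. Processed pseudogenes were matched to protein-coding transcripts of the annotation with minimap2 2.31, keeping matches over at least 80% of the pseudogene. That pseudogene analysis, the length trend and the tests with 1 gene per shared model were added after the data were seen.

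On simulated counts with the means of the real genes, the binomial test recovered 21 of 74 genes (28.4%) changed 1.5-fold, 40 of 71 (56.3%) changed 2-fold and 37 of 49 (75.5%) changed 4-fold, all in the right direction, and called 2 of 9976 unchanged genes, over 10170 tested genes. The list test at an unadjusted 0.05 called 13 of 200 random lists and 50 of 50 lists shifted 1.5-fold. The isoform test recovered 86 of 200 shares moved by 20 points, 67 of 83 in genes with at least 100 reads per library, and called 7 of 3963 unchanged genes. All simulated counts held counting error alone, without the length trend or changes of model class between libraries. The few false calls therefore describe the tests under their own error model, and not the calls made in these libraries.

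Alternatives were edgeR 4.0.16 TMM factors and DESeq2 1.42.0 size factors, both used for scaling only, other read minimums, a pseudocount of 0.1, sets of model classes, chain matching with ends within 100 bases, a chi-square test with 10000 simulated tables, and leaving out each replicate. Alternatives added after seeing the data were an expected split that follows the length trend, random lists matched on length as well, 1 gene per shared model under 3 overlap rules (1 base with the span of the gene's deposited models, 50% of the locus, or 1 base with the annotated gene), 1-exon models kept apart, and counting the Genomic class in the isoform test. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3. Splice site sequences and the base content next to 3′ ends were planned but not run, since they need a genome sequence, which was not used here.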

Results

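Long reads of total RNA were counted per transcript model in C2C12, a mouse myoblast line that divides in rich medium and fuses into myotubes when serum is withdrawn. The labels put 2 libraries, biological replicates 1 and 2, in 1 group of C2C12 myoblasts. With 1 group there were no conditions to compare, so each test compared these 2 libraries. Replicate 1 held 2591602 reads on 156411 transcript models, and replicate 2 held 2576794 reads on 151813 models. Of these reads, 2577735 (99.5%) and 2562327 (99.4%) lay on annotated genes. At least 1 read was counted for 13067 genes in replicate 1, 13153 in replicate 2 and 12021 in both, of which 11231 were protein-coding. Gene levels are given as CPM over the reads on annotated genes, as mean ± SD with n = 2 libraries. A gene with 0 reads was below 1.16 CPM in replicate 1 and 1.17 CPM in replicate 2, the level of 3 counts. Intervals and floors cover counting error only.

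The most abundant transcripts included some of the actin and intermediate filament skeleton, of glycolysis and of translation. Actg1, cytoplasmic gamma-actin, reached 18348 ± 928 CPM, Vim, the intermediate filament protein vimentin, 10990.2 ± 943 CPM, and Tpm4, a tropomyosin, 3073 ± 97.9 CPM. Of the glycolytic enzymes, Pkm stood at 13210.4 ± 331 CPM, Eno1 at 8523 ± 951 CPM and Ldha at 4712 ± 846 CPM. The elongation factors Eef1a1 and Eef2 reached 9007 ± 879.5 and 8294 ± 983 CPM, and the ribosomal protein gene Rpl4 3075 ± 841 CPM. The tubulins Tuba1b, Tubb5 and Tuba1a reached 6520.3 ± 973, 4129.9 ± 100.3 and 3397 ± 183 CPM. Spp1, the secreted phosphoprotein osteopontin, stood at 6792 ± 2087 CPM, Anxa2, a calcium-dependent membrane-binding annexin, at 4639 ± 1483 CPM, and Lmna, which encodes lamins A and C, at 5617 ± 615 CPM. The remaining genes among the 20 nuclear genes with the highest mean were the chaperone gene Hsp90ab1 (3975 ± 327 CPM), the ribonucleotide reductase gene Rrm2 (3851 ± 63.2 CPM), P4hb, a protein disulfide isomerase (3407 ± 238 CPM), the ATP synthase gene Atp5a1 (2976 ± 167 CPM) and the processed pseudogene Gm15459. Gm15459 (ENSMUSG00000100801.1, chromosome 5, 5781615 to 5783555, mm10) carried the highest count of all at 18986 ± 1248 CPM, and its sequence was 99.7% identical to a transcript of the chaperone gene Hspa8, which itself held 183 ± 23.3 CPM. In each library the 20 genes with the most reads took 13.8% and 15.04% of the reads on annotated genes.

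Most myoblast genes were read and the late differentiation genes were mostly not detected. Of the 25 genes of myogenic regulators and myoblast identity, 21 had any read and 18 had reads in both libraries. Des, the muscle intermediate filament desmin, stood at 1620.4 ± 86.1 CPM, Cdh15, a cadherin of muscle precursors, at 227 ± 21.9 CPM, and Itga7, a laminin receptor subunit of muscle, at 159 ± 5.66 CPM. Myod1 (ENSMUSG00000009471.4, chromosome 7, 46376474 to 46379099), the transcription factor that commits cells to muscle, stood at 126 ± 2.46 CPM and its relative Myf5 at 19.6 ± 2.94 CPM. Pax7, a satellite cell factor, had 10 and 4 reads (2.72 ± 1.64 CPM). It stood at 1.24 CPM without reads of the incomplete splice match (ISM) and Genomic model classes. Myog, the factor that drives differentiation, the embryonic myosin gene Myh3 and the muscle creatine kinase gene Ckm had 0 reads in each library, so they were below the level of 3 counts. Of the 43 genes of differentiation, fusion and sarcomere, 16 had any read and 9 had reads in both libraries. The 3 highest were Eno3, the muscle enolase, at 1730.4 ± 403 CPM, Chrna1, an acetylcholine receptor subunit, at 141 ± 11.3 CPM and the cardiac and embryonic troponin gene Tnnt2 at 50.4 ± 14.8 CPM. The list as a whole stood at 1939 ± 431 CPM, so Eno3 made up most of it.

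**Figure D1:**
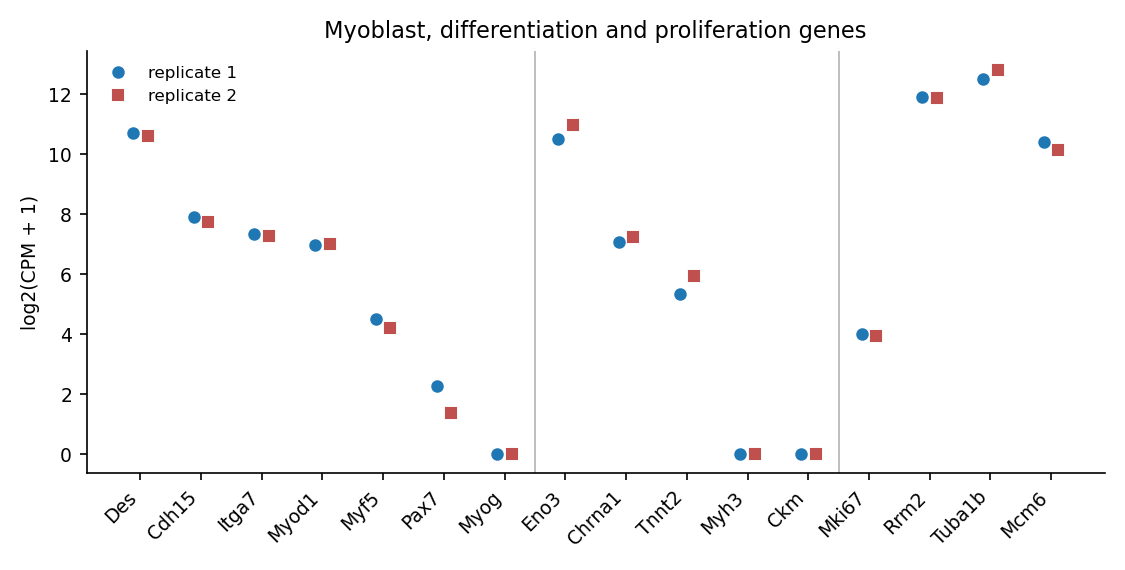
Levels of myoblast (left), differentiation (middle) and proliferation (right) genes as log2(CPM + 1) on the vertical axis, with 1 circle for replicate 1 and 1 square for replicate 2. Myog, Myh3 and Ckm lie at 0 in each library, and Rrm2 and Tuba1b are the highest of the proliferation genes drawn.

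The cell cycle and DNA replication list was expressed in full, with all 34 genes read in both libraries at a joint 21128 ± 288 CPM. Beside Tuba1b and Rrm2, its highest member was Mcm6, a subunit of the replicative helicase, at 1249.8 ± 180.1 CPM. Mki67, a proliferation marker, stood at 14.8 ± 0.488 CPM. Its level was only 1.03 CPM without reads of the ISM and Genomic model classes, which held most of its reads. The cell cycle exit list summed to 248 ± 11.9 CPM over 12 genes, led by the cyclin gene Ccnd3 at 155 ± 2.03 CPM, Btg1 at 34.6 ± 8.66 CPM and the kinase inhibitor gene Cdkn2c at 22.9 ± 9.26 CPM. Extracellular matrix and adhesion genes summed to 8576 ± 40.1 CPM, led by the galectin gene Lgals1 (2725 ± 622 CPM), the collagen gene Col3a1 (1065 ± 149.6 CPM) and the integrin gene Itgb1 (1035 ± 171 CPM). Of the immediate early and serum response genes, Junb reached 1026 ± 113 CPM, Ccn1 707 ± 86.4 CPM and Ier2 529.7 ± 68.8 CPM. The stress genes were led by the thioredoxin reductase gene Txnrd1 (1177 ± 356 CPM), the endoplasmic reticulum chaperone gene Hspa5 (1097 ± 119 CPM) and the autophagy receptor gene Sqstm1 (607 ± 2.02 CPM). Id3, Pdgfrb and Id2 led the growth factor and Notch list at 174 ± 67.0, 97.2 ± 23.8 and 82.9 ± 31.2 CPM. Igf2 had 0 reads in each library. Hnrnpa1, Srsf3 and Srsf6 led the splicing regulators at 2251 ± 117, 838 ± 123 and 628 ± 16.9 CPM.

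Markers of other cell types were low or not detected, and a few regulators of bone, fat and cartilage were read. The 22 markers of other cell types summed to 6.04 ± 1.95 CPM, with Ly6a at 3.12 ± 1.66 CPM, Pdgfra at 1.36 ± 0.269 CPM (0.622 CPM without ISM and Genomic reads) and Cdh1 at 0 and 3 reads. Of the 13 bone, fat and cartilage genes 5 had any read, led by Pparg, a regulator of fat cell formation, at 71.98 ± 1.35 CPM, Sox9, a cartilage regulator, at 35.6 ± 0.124 CPM and Runx2, a bone regulator, at 11.5 ± 1.33 CPM. Without ISM and Genomic reads Runx2 stood at 3.52 CPM. The 12 interferon response genes summed to 27.6 ± 2.08 CPM, with Ifi35 at 7.40 ± 2.23 CPM and Ifit1 at 3 and 2 reads. Mitochondrially encoded genes held 0.00183% ± 0.000267 of the reads, mostly on mt-Rnr2 (15.4 ± 3.51 CPM), with mt-Co1 at 1.56 ± 0.00660 CPM and mt-Nd1 at 0.584 ± 0.278 CPM. These were 52 and 42 reads in all, with 1 and 2 on mt-Nd1, which lay below the level of 3 counts. The read filters are not given, so how far this share reflects the RNA of the cells is not known. Long noncoding RNA genes of all names held 0.361% ± 0.00136 of the reads. Of the listed ones, Gas5 reached 25.3 ± 5.06 CPM, Pvt1 16.9 ± 1.85 CPM, Dubr 14.2 ± 0.215 CPM, Malat1 9.74 ± 5.54 CPM and H19 2.34 ± 0.560 CPM, and Meg3 had 0 reads in each library.

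The 2 libraries had similar gene levels, with a difference that followed transcript length. Short transcripts, those of ribosomal proteins among them, were higher in replicate 2, and long ones were higher in replicate 1. Over 10191 genes with at least 10 reads, Pearson's r of log2(CPM + 1) was 0.974 (95% bootstrap interval 0.973 to 0.975) and Spearman's rho 0.974, across genes, which are not independent replicates. The median log2 ratio of replicate 2 over replicate 1 was 0.56 for the 133 genes under 500 bases, 0.60 for 454 genes of 500 to 1000 bases and 0.50 for 995 genes of 1000 to 1500 bases. It was 0.14 for 1378 genes of 1500 to 2000 bases, −0.12 for 3054 genes of 2000 to 3000 bases and −0.21 for 613 genes of 5000 bases or more. Across genes the ratio and the length had a Spearman's rho of −0.484, and −0.567 over the 4204 genes with at least 200 reads. The median model length over reads was 2486 bases in replicate 1 and 2297 bases in replicate 2. The spread of the log2 ratio over genes was 0.48 (SD), and 93.5% of the 1058 genes with at least 1000 reads lay within 1.5-fold.

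**Figure D2:**
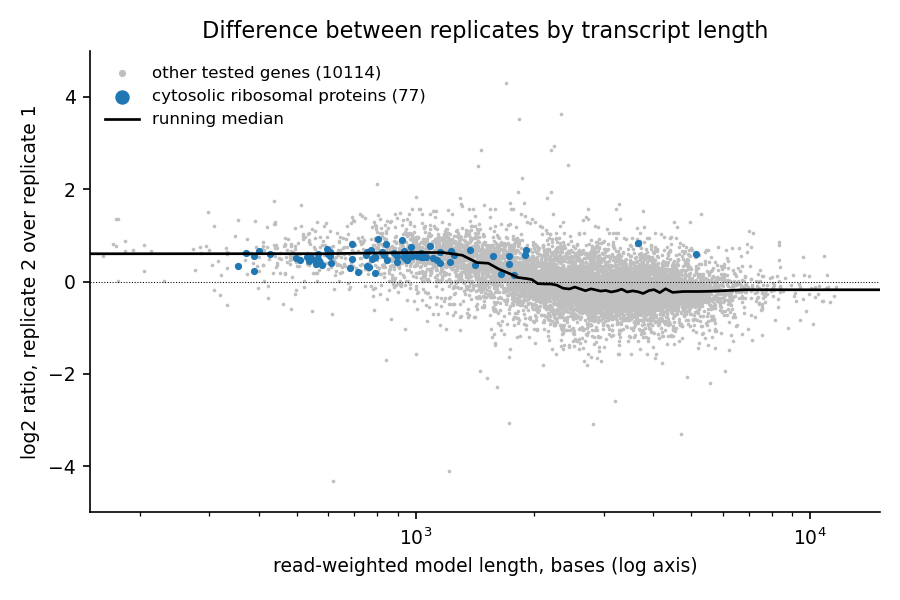
Log2 ratio of replicate 2 over replicate 1 (vertical axis) against read-weighted model length in bases (log axis) for the tested genes, with the 77 ribosomal protein genes in blue and the running median as a line; the axes leave out a few very short, very long or more extreme genes. The running median falls from above 0 for short transcripts to below 0 for long ones.

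An exact two-sided binomial test of each gene's split of reads put 1901 of 10191 genes (18.7%) past an adjusted p of 0.05, of which 935 were higher in replicate 2, 966 were higher in replicate 1 and 199 differed by at least 2-fold. The division of these calls rested on the scaling: 49.2% were higher in replicate 2 with library totals, 66.1% (1098 of 1662 genes) with edgeR TMM factors and 65.4% (1089 of 1666) with DESeq2 size factors. With the expected split set by the length trend, an alternative chosen after seeing the data, 543 genes passed, 424 of them among the 1901. The chi-square of the gene counts over its degrees of freedom was 6.46, where counting error alone gives 1. The test takes counting error as the only error, so its p-values describe these libraries and not C2C12 cultures in general.

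**Figure D3:**
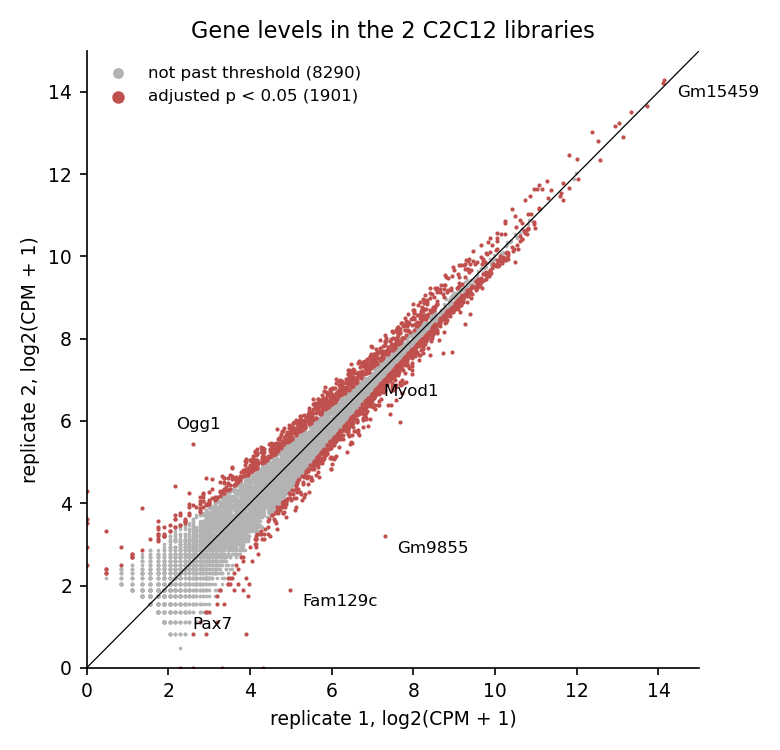
Levels of the 10191 tested genes as log2(CPM + 1) in replicate 1 (horizontal axis) and replicate 2 (vertical axis), with the 1901 genes past the threshold in red and the line of equal levels. Gm9855 and Fam129c lie far to the side of replicate 1 and Ogg1 far to the side of replicate 2.

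All 77 cytosolic ribosomal protein genes had the higher level in replicate 2 under library totals, and 61 of them passed the test (64 adjusted over the list alone). Both other scalings raise all ratios by 0.07, so this direction could not turn under them. Among those past the threshold, the log2 ratio was 0.68 for Rplp0 (adjusted p 1.13e-152, binomial), 0.68 for Rpsa and 0.57 for Rpl4. Their levels were 2571 ± 838, 913 ± 298 and 3075 ± 841 CPM. After subtraction of the length trend, the ratio was 0.19 for Rplp0, 0.61 for Rpsa and 0.22 for Rpl4. Of the 29 actin cytoskeleton genes 20 passed, 15 higher in replicate 2 and 5 higher in replicate 1 (20 adjusted over the list alone). The actin-severing factor gene Cfl1 had the largest ratio (0.77), with Actg1 at 0.10 and Vim at 0.18. Once the length trend was subtracted, Cfl1 was at 0.89, Actg1 at 0.05 and Vim at 0.22. Tpm4 passed at -0.06, a value whose sign turned under both other scalings. Among 17 lists, the median ratio stood apart from that of 10000 random lists matched on expression for the ribosomal proteins (0.54, percentile 100, adjusted permutation p 0.0034, from a raw p of 0.0002, the smallest possible) and for the actin cytoskeleton (0.21, percentile 99.97, adjusted permutation p 0.0085). Matched on length as well, the ribosomal proteins lay at percentile 14.5 (adjusted permutation p 0.942), the actin genes at 99.4 (adjusted permutation p 0.211), and 0 of the 17 lists were past the threshold. Random lists were drawn from all tested genes and could hold members of the list itself, which pulls their medians towards it.

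The medians of the other lists did not stand apart (adjusted permutation p from 0.295 upward). The ratios of single genes here and in the next paragraph hold the length trend unless it is said to be taken out. Of the 34 cell cycle genes 19 passed, 8 higher in replicate 2 and 11 higher in replicate 1 (24 adjusted over the list alone), with Birc5, an inhibitor of apoptosis that acts in mitosis, at 0.76 and Mcm6 at -0.29. With the length trend taken out, Birc5 was at 0.13 and Mcm6 at -0.10. Of 29 matrix genes 9 passed, 2 higher in replicate 2 and 7 higher in replicate 1 (10 over the list alone), with Timp1, an inhibitor of matrix proteases, at 0.88, Lgals1 at 0.47, Col3a1 at -0.29 and Itgb1 at -0.34. Less the length trend, Timp1 was at 0.26, Col3a1 at -0.07 and Itgb1 at -0.09, and Lgals1 turned to -0.15. Of the 16 glycolysis genes 9 passed, 6 and 3 (11 over the list alone), with Tpi1 at 0.55, Ldha at 0.37 and Pkm at -0.05, which turned sign under both other scalings. Taking out the length trend left Tpi1 at 0.26, Ldha at 0.05 and Pkm at 0.10. Of 14 growth factor and Notch genes 6 passed, 4 and 2 (7 over the list alone), where Id1, Id2 and Id3, dominant-negative partners of helix-loop-helix factors, stood at 1.08, 0.78 and 0.80 and Pdgfrb at -0.50. The median of this list turned from 0.03 to −0.37 without ISM and Genomic reads (adjusted permutation p 0.678 and 0.0907). Of 22 splicing regulators 8 passed, 4 and 4 (9 over the list alone), with Srsf2 at -0.79, Srsf3 at 0.30 and Hnrnpa1 at 0.11. Of 14 immediate early genes 4 passed, 3 and 1 (5 over the list alone), with Ier2 at 0.27, Junb at 0.22 and Ccn1 at -0.25. Without the length trend, Ier2 turned to -0.13, with Junb at 0.13 and Ccn1 at -0.23.

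Few genes of the remaining lists passed, and for these the count adjusted over the list alone was the same as over all genes. Of 17 myogenic genes 3 passed, all higher in replicate 1, among them the transcription factor gene Mef2d (-0.55) and Des (-0.11), while Myod1 was at 0.04 (adjusted p 0.910, binomial). Taking out the length trend left Mef2d at -0.31 and turned Des to 0.09. Of the differentiation genes 5 were tested and 2 passed, Eno3 (0.48) and Tnnt2 (0.60), each higher in replicate 2. Less the length trend, these ratios were 0.07 and 0.09. In the cell cycle exit list Cdkn2c passed (-0.81) of 8 tested. Txnrd1 (-0.63) and Hspa5 (-0.22) passed of 16 stress genes, and Malat1 (1.10) of 9 long noncoding RNA genes. Without the length trend, Cdkn2c was at -0.66, Txnrd1 at -0.44 and Hspa5 at 0.004. None passed of 2 interferon response genes, 3 bone, fat and cartilage genes, 1 marker of other cell types and 1 mitochondrially encoded gene.

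The largest differences between the libraries were of Gm9855, a processed pseudogene (-4.10, 405 and 21 reads), and Fam129c (-3.08, 79 and 7 reads) on the side of replicate 1. On the side of replicate 2 they were of Ogg1, which encodes a DNA glycosylase for oxidised guanine (2.85, 13 and 109 reads), and Gm49325 (2.25, 9 and 52 reads). Gm9855 lies at ENSMUSG00000085666.3, chromosome 10, 42054113 to 42055306 and Ogg1 at ENSMUSG00000030271.14, chromosome 6, 113326972 to 113335068. When each shared intron chain and each overlapping 1-exon locus was given to 1 gene, chosen after seeing the data, the ratios of Gm9855, Fam129c, Ogg1 and Gm49325 became −0.25, −1.06, 0.36 and 0.53, and that of the pseudogene Gm9825 went from -1.69 to 0.14. The locus joined to Gm9825 shared 1 base with it, and the locus joined to Gm9855 lay 1281 bases from the annotated gene, within the span of the gene's deposited models. With an overlap of at least 50% Gm9825 stayed at −1.69, and with annotated gene positions Gm9855 stayed at −4.10. The other 8 of the 10 largest on the side of replicate 1 were Gm9825, Cachd1, Edem3, Smarcd2, Tmem245, the kinase gene Stk11, and the RNA-binding protein genes Hnrnpu and Hnrnpll, from -1.69 to -1.24. The other 8 on the side of replicate 2 were Rps19-ps6, Rab4b, Hmgn3, Tmem147, Chchd6, Tomm6, Ubl5 and Coq7, from 1.74 to 1.35. Hnrnpu, the longest of the 10 in replicate 1 by read-weighted model length, had 1261 and 522 reads (adjusted p 1.19e-66, binomial). Its ratio was -1.26, and -1.08 with the length trend taken out.

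Several housekeeping genes had fewer reads than an intronless copy of them. Of 154 processed pseudogenes with at least 10 reads, 145 matched a protein-coding transcript over at least 80% of their length, with a median identity of 99.7%, and 26 held more reads than the gene they copy. These 26 held 90.4% of the reads of the matched pseudogenes. Gm15459 had 46667 and 50911 reads against 428 and 510 for Hspa8. Rpl3-ps1 had 5556 and 8799 reads against 182 and 202 for Rpl3, and Rps2-ps10 had 5383 and 8120 against 45 and 66 for Rps2. Gm13394 had 3526 and 5875 reads against 20 and 22 for Gapdh, a glycolytic enzyme gene. Gm10123, with 1578 and 2291 reads, held fewer than Ppia, with 1702 and 2503. The levels of these pairs are uncertain, since near-identical sequences can share reads. Processed pseudogenes took 2.80% of the reads in replicate 1 (Wilson 95% interval 2.78 to 2.82) and 3.46% in replicate 2 (3.43 to 3.48). These shares were not adjusted for the length trend. The median log2 ratio of the 154 processed pseudogenes was 0.56. For comparison, it was 0.56 for all genes under 500 bases and 0.60 for all of 500 to 1000 bases.

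Annotated transcripts carried most reads. Models of the class Known took 84.1% ± 0.651 of the reads and incomplete splice matches (ISM, a run of the introns of an annotated transcript) 5.39% ± 0.0994. The class NIC, named for unannotated combinations of annotated splice sites, took 5.53% ± 0.305. The class NNC, named for an unannotated splice site, took 3.84% ± 0.245. Reads called Genomic took 0.671% ± 0.0216, Antisense 0.375% ± 0.00882 and Intergenic 0.141% ± 0.0284 (SD, n = 2). Over models with at least 5 reads the NNC share was 1.84%. Of the ISM reads 53.8% ± 0.238 matched the 3′ part of a transcript (suffix) and 39.7% ± 0.637 the 5′ part (prefix). By intron chain, 85.3% ± 0.321 of the Known models of a library were also models of the other library, and 47.5% ± 0.824 of ISM, 43.6% ± 2.27 of NIC and 26.7% ± 0.451 of NNC models. The 63069 shared chains, of 145221 in replicate 1 and 140091 in replicate 2, carried 96.1% and 96.3% of the reads of multi-exon models. In all, 63.3% and 63.5% of the models had 1 read, and of models with at least 5 reads 97.2% of NNC to 99.7% of Known models were found. The class name itself was not fixed between libraries: 3942 of 29658 shared NIC or NNC chains (13.3%, Wilson 95% interval 12.9 to 13.7) were NIC in 1 library and NNC in the other. In Hnrnpk, chains that were NIC in 1 library held an intron with an unannotated end. NIC reads can therefore include unannotated splice sites.

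**Figure D4:**
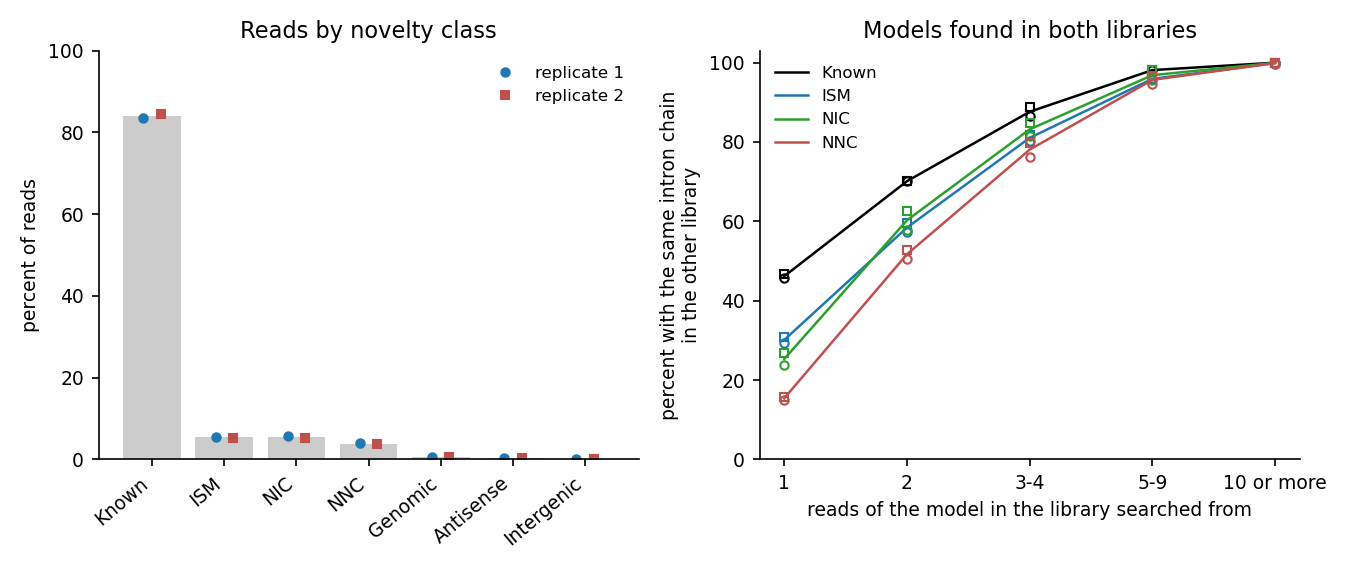
Left, percent of reads per novelty class, with bars for the mean of the 2 libraries and points for each library. Right, percent of multi-exon models whose intron chain was found in the other library (vertical axis) by the reads of the model (horizontal axis), with lines for the mean and points for each library; NNC models with 1 read are the lowest.

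The 15 genes of the isoform list with the most reads used the forms listed here. Their shares were mostly close between the libraries, although Lmna passed the test. Over the 37 tested genes of the list, the median absolute difference of the top share was 3.04 percentage points. Pkm used Pkm-201 for 89.3% ± 0.0995 of its reads and Pkm-202 for 7.32% ± 0.192. Pkm-201 carries the downstream exon (chromosome 9, 59675568 to 59675734) and Pkm-202 the upstream exon (59675029 to 59675195) of the mutually exclusive pair that separates the form of dividing cells from that of adult muscle. Lmna used Lmna-203, with the 10 exons of lamin C, for 53.6% ± 2.19 and Lmna-201, with the 12 exons of lamin A, for 43.5% ± 2.28. Of the tropomyosins, Tpm1 used Tpm1-216 (79.8% ± 0.640), Tpm1-213 (7.70% ± 0.0392) and Tpm1-211 (6.60% ± 0.131), Tpm3 used Tpm3-201 (91.1% ± 0.225) and Tpm4 used Tpm4-201 (97.1% ± 0.0581). Cttn, an actin-binding protein gene, used Cttn-202 (54.1% ± 0.345), Cttn-201 (18.97% ± 1.01) and an NNC model (7.13% ± 0.269). Ptbp1, a splicing repressor gene, was divided between Ptbp1-216, with 14 exons (44.5% ± 0.909), and Ptbp1-206, with 13 exons (43.4% ± 0.569). Bin1, a membrane-bending protein gene, used Bin1-205 (55.7% ± 2.78) and Bin1-206 (34.3% ± 3.23). Hnrnpdl gave 7.52% ± 0.709 of its reads to a transcript annotated for nonsense-mediated decay. In Actn4, Slc25a3, Srsf3, Cd44, Tra2b, Cdc42 and Hnrnpdl 1 model took from 73.4% to 95.01% of the reads.

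**Figure D5:**
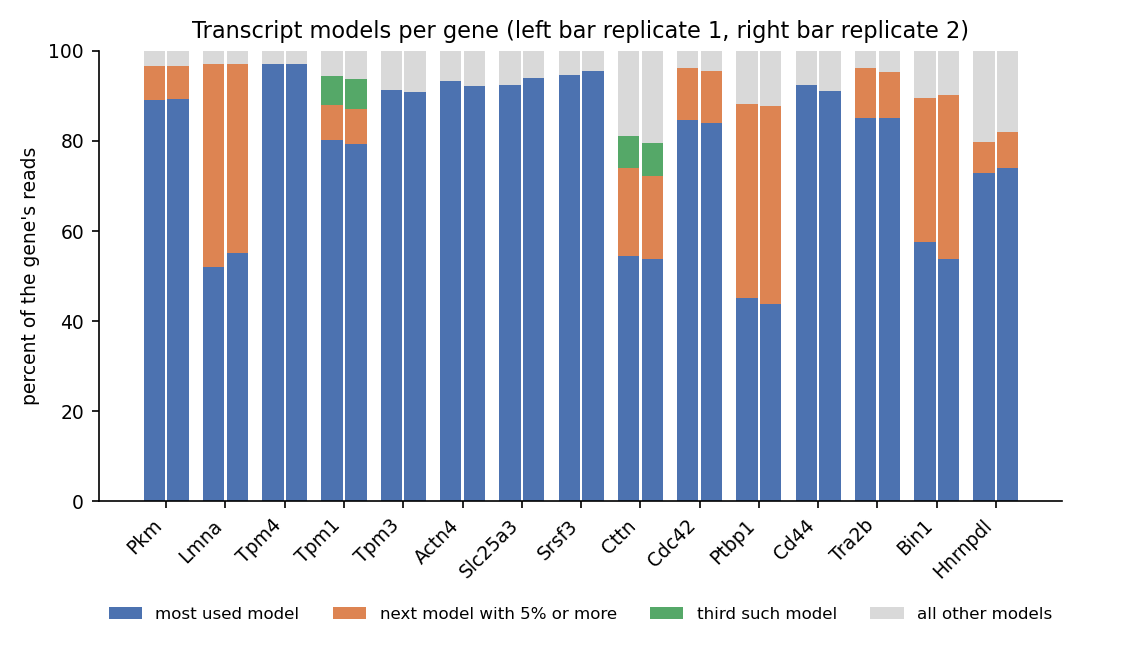
Percent of each gene's reads (vertical axis, from 0) on its transcript models for the 15 genes of the isoform list with the most reads, replicate 1 in the left bar and replicate 2 in the right bar of each pair. Colours stand for the models with at least 5% of the reads, and grey for all others.

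Between the libraries, the share of the most used model differed past the threshold in 22 of 4163 genes, by Fisher's exact test with Benjamini-Hochberg adjustment. However, 12 of these were lost once reads of the Genomic class were counted. That alternative, chosen after seeing the data, gave 11 genes, 10 of them among the 22. Zcchc24 had 83 reads on an unannotated 1-exon ISM model in replicate 1 (81.4% of its reads) and 0 in replicate 2, where 82 1-exon reads of the gene were called Genomic. With these counted, the shares were 81.4% and 80.4% (adjusted p 1, exact). Selenot, Foxm1, Fam171a1 and Ckap4 were lost in the same way. Macf1 was lost too (adjusted exact p 0.575), and so was Dlk2, which has 0 such reads and whose adjusted exact p moved from 0.0399 to 0.0711. The shares of Dlk2-203 stayed the same, at 79.5% and 53.2% in replicates 1 and 2. Of 106 genes with at least 20 such 1-exon reads in each library, 22 had them all as ISM in 1 library and all as Genomic in the other. Of the 10 largest differences, those of 3 genes stayed past the threshold when the Genomic class was counted. Rbbp4, a histone-binding protein gene, used Rbbp4-201 for 50.2% and 71.9% of its reads in replicates 1 and 2 (adjusted exact p 9.77e-06). Gtpbp4, a GTPase gene of ribosome assembly, used Gtpbp4-204 for 61.2% and 41.7% (adjusted exact p 1.22e-06), a share of 93.4% on average without ISM models. Fastkd5 used Fastkd5-201 for 97.1% and 48.4% (adjusted exact p 0.00211), with 15 of 31 reads on a NIC model in replicate 2. Of the isoform list 46 genes had enough reads, 37 were tested and Lmna passed (2 adjusted over the list alone), with Lmna-203 at 52.0% and 55.1%. Over all tested genes the median absolute difference was 4.28 percentage points.

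Some well-expressed genes were read mainly from models that are not in the annotation. Among NIC and NNC models found in both libraries, the most reads, 3718 and 3705, lay on an NNC model of the chaperonin gene Cct6a, which took 89.4% ± 0.372 of the gene's reads. Its unannotated intron ran from 129794561 to 129844936 on chromosome 5, and neither end of it is an annotated intron end. An NNC model of the protease gene Capn2 took 96.1% ± 0.108, with an unannotated intron from 182481659 to 182484185 on chromosome 1. In Hnrnpk, 2 models with the same unannotated intron (chromosome 13, 58393775 to 58394059) took 43.2% ± 1.58 and 22.5% ± 1.42, and each was NIC in 1 library and NNC in the other. NIC models took 94.9% ± 0.585 of Oaz1, which encodes the antizyme of ornithine decarboxylase, 79.5% ± 2.49 of Arhgap22, 93.3% ± 0.129 of Itprip, 83.4% ± 3.78 of the septin gene Sept7 and 98.0% ± 0.427 of the prohibitin gene Phb2. An NNC model took 92.9% ± 0.469 of Chmp1a, which encodes a subunit of the ESCRT-III membrane complex. Each end of the unannotated intron of Itprip is itself an annotated intron end, and the intron ended 5 bases from the end of another, annotated intron. The sequence of the splice sites was not analysed here.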

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

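No test was run on the results in this part, so none was chosen after they were seen, and no biological explanation was tested, because the samples form 1 group.

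Reads at loci outside annotated genes, which the gene comparisons leave out, numbered 13804 in replicate 1 (0.533% of the reads) and 14366 in replicate 2 (0.558%), far above the 3 counts that a count of 0 allows. A 2-exon intergenic locus on chromosome 17 (34995592 to 35000353, minus strand), 634 bases from Vars, had 642 and 462 reads. Another 2-exon intergenic locus on chromosome 13 (21812929 to 21820124, plus strand), 782 bases from the histone gene Hist1h4m, had 581 and 580 reads. A locus that shared 1 base with the pseudogene Gm7335 on its strand had 268 and 316 reads. A locus that shared 1 base with Gm9825 and another 1281 bases from Gm9855, each on the strand of the gene, were named intergenic in replicate 2 alone, with 412 and 318 reads. Given to the genes, a choice made after the data were seen, they brought Gm9825 to 522 and 571 reads and Gm9855 to 405 and 339 reads in replicates 1 and 2, but whether the libraries read the same molecules there was not tested. The most read antisense locus lay opposite the noncoding RNA gene Gm26917 on chromosome 17 (39843013 to 39846245), with 1421 and 855 reads. Others lay opposite Mrps6 and Slc5a3 (294 and 273 reads), the septin gene Sept2 (227 and 274 reads), Mcc (224 and 203 reads) and Rbms2 (173 and 158 reads).

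Spike-in reads, also outside the gene comparisons, numbered 63 in replicate 1 and 101 in replicate 2, above the 3 counts that a count of 0 allows. Of these, 25 and 36 were ERCC and 38 and 65 SIRV reads. Of the SIRV reads 1 and 4 were on Known models and 25 and 28 on NNC models. Such counts are too low to scale the libraries by them.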

How the results depend on the processing

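The length trend in the gene test, length-matched lists, 1 gene per shared model, separate 1-exon models and counting the Genomic class in the isoform test were chosen after the data were seen. Of 254 comparisons of a result with an alternative, over 154 results, 193 kept their direction and side of the threshold or moved by less than 1 SD, 55 moved, 1 lost its call and 5 turned direction, among them the ribosomal protein list, which lost its call as well (adjusted permutation p 0.942 when matched on length) with its median at 0.54. Leaving out 1 of 2 replicates cannot move a mean by 1 SD, so it says nothing about stability.

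The replicate correlation was 0.981 without a read minimum, 0.971 at 50 reads and 0.966 with a pseudocount of 0.1. Genes detected in both numbered 9835 at 5 reads and 11690 without the Genomic class. Genes differing numbered 1662 to 1917 under the alternatives fixed beforehand and 1875, 1878 and 1879 with 1 gene per shared model, but 543 with the length trend, whose construction takes the trend out. Of 68 list comparisons fixed beforehand 66 gave the same call and side of percentile 50, but those under other scalings say nothing about stability, since a scaling shifts a list and its random lists alike. The medians themselves turned sign under both other scalings for cell cycle, cell cycle exit, stress, splicing and bone, fat and cartilage genes, and from 0.12 to −0.03 for immediate early genes with Known, NIC and NNC models only. Growth factor and Notch genes moved to percentile 0.745 (median −0.37, adjusted permutation p 0.0907) with Known, NIC and NNC models only, where their median lies between members on either side, and the 2 interferon genes to 44.2. Matched on length, the percentile was 46.8 for differentiation, 14.5 for ribosomal proteins, 45.7 for interferon and 99.4 for actin genes (adjusted permutation p 0.211).

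Class shares with at least 5 reads per model were Known 89.8%, ISM 3.78%, NIC 3.83%, NNC 1.84%, Genomic 0.435%, Antisense 0.217% and Intergenic 0.102%. For multi-exon models they were NIC 5.84%, Genomic 0.0432%, Antisense 0.0170% and Intergenic 0.0564%. Models with at least 5 reads were found in the other library for 99.7% of Known, 97.6% of ISM, 98.2% of NIC and 97.2% of NNC, so low counts limit the matching. The classes also differed at equal counts in the library searched from. Equal counts there need not mean equal abundance, so whether anything beyond low counts limits the matching is not decided. With 1 read, 46.2% of Known, 30.1% of ISM, 25.3% of NIC and 15.4% of NNC models were found. With ends within 100 bases, 35.8% of ISM, 34.0% of NIC and 20.96% of NNC were found; Known models take their ends from the annotation.

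Genes with differing isoform use numbered 36 by the chi-square test (20 of them among the 22), for which the cause was not tested, and 11 with the Genomic class counted (10 of the 22), in part since 1-exon reads of some genes were ISM in 1 library and Genomic in the other; Dlk2 was lost without such reads, and the genes tested rose from 4163 to 4384. They numbered 29 at 10 reads, 20 at 50 reads, 32 with 1-exon models apart, and 21 without ISM models, of which 7 were among the 22. Without ISM and Genomic reads, 19 of 97 gene levels moved by over 1 SD and 6 by over 1.5 times, to 25.1 CPM for Mef2d, 3.52 for Runx2, 0.622 for Pdgfra, 1.24 for Pax7, 1.03 for Mki67 and 7.05 for Ogg1. Without ISM models, 12 of 23 isoform shares moved and 22 were higher. Depth limits the isoform calls: of simulated moves of 20 points, 86 of 200 were recovered over all genes and 67 of 83 with at least 100 reads in each library.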

Other observations

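The tests of the length trend, with the lists matched on length, and those of the pseudogenes were added after the data were seen, and the test with 1 gene per shared model under each of its overlap rules, the subset with a larger expected difference, and the interval rules of the own-transcription test and of both tests on the largest differences were chosen only after their own results were seen.

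Among reads on annotated transcripts, 95.5% ± 0.496 (SD, n = 2) lay on protein-coding transcripts, 0.293% ± 0.00746 on transcripts annotated as retained introns, 0.264% ± 0.0168 on transcripts annotated for nonsense-mediated decay and 0.0598% ± 0.00535 on lincRNAs. Protein-coding genes held 96.4% ± 0.457 of all reads on annotated genes. Of the 4163 genes tested for isoform use, the most used model was annotated in 3491 (83.9%), ISM in 336, NIC in 256, NNC in 62 and an unannotated 1-exon model in 18.

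The log2 ratio of replicate 2 over replicate 1 fell with transcript length across genes, with a Spearman's rho of −0.484. GC content as the whole cause is argued against, since the correlation with length holding GC content was −0.511 (95% bootstrap interval −0.528 to −0.495, 9678 genes). A difference in ribosomal protein genes apart from length is not decided by their percentile of 14.5 among lists matched on length and expression. Those lists were drawn from all tested genes, so they could hold the ribosomal protein genes themselves. The ribosomal protein median, 0.54, was near the 0.60 of all 454 genes of 500 to 1000 bases. A candidate explanation is recovery of molecules that depends on length: in 725 genes with a shorter and a longer annotated model, the longer had the lower ratio in 55.3% (Wilson 95% interval 51.7 to 58.9). The size was well short of the trend between genes, with a median difference of −0.06 where the trend gives −0.22, and −0.16 where it gives −0.67 in the 301 genes with the larger expected difference, of which 62.1% went that way. Model length is not read length, and a difference between the cultures that follows length stays open, as it was not tested.

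Processed pseudogenes such as Gm15459 held more reads than the gene they copy. If reads of copied genes were placed at the copies, adding them back should narrow the spread of ribosomal protein levels, and the SD of the log2 levels fell to 0.825 of its value (95% bootstrap interval 0.665 to 0.992), as low in 0.12% of shuffled additions but short of the fall set beforehand. If the copies were transcribed themselves and the genes unaffected, genes with a copy of at least 100 reads should not be lower, and their median differed from that of the others by −0.24 log2 units (28 against 49 genes, 95% interval −1.60 to 0.51, two-sided permutation p 0.362), and by 0.74 after adding. The p met what was set beforehand for this explanation, but the interval also holds a fall of 1 log2 unit. Misplaced reads and own transcription cannot be told apart with 77 genes of such spread and without the alignments, which were not analysed here. No biological explanation other than own transcription was tested.

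The 20 genes with the largest differences between the libraries, 10 in each direction, had a median absolute log2 ratio of 1.44. With each shared model given to 1 gene the median was 0.922 of its value (95% bootstrap interval 0.752 to 0.989), and 5 of the 20, Gm9855, Fam129c, Gm9825, Ogg1 and Gm49325, fell by over 1 log2 unit, so the naming of genes may account for these, though Gm9825 was joined to its locus by 1 base and Gm9855 only through the span of its deposited models. Under an overlap rule of 50% for 1-exon loci, which was tried first, 4 of the 20 fell that far, without Gm9825, and with annotated gene positions 4, without Gm9855, with the median at 0.943 of its value under each. Less the length trend, the median was 0.783 of its value (95% bootstrap interval 0.691 to 0.875). For the set as a whole neither explanation can be told apart from other causes, since each interval runs across the bound of 80% set for it, and no biological explanation was tested.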
